A study of Mus musculus with 11 samples.

How the data were processed

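The libraries were made from polyadenylated RNA with a TruSeq version 2 kit from 100 ng of RNA with an integrity number over 8, and sequenced as paired ends. Per the submitters' processing notes, reads were converted with bcl2fastq 1.8.4, aligned to mm10 with STAR 2.3.0 and counted with featureCounts 1.4.3. The deposited table holds raw counts per Ensembl gene for the 11 libraries, and per the file headers each mate of a pair was counted as a read, over exons grouped by gene, with no strand, overlap or multi-mapping option. Reads shared by near-identical copies, such as Ly6c1 and Ly6c2 or Hspa1a and Hspa1b, are therefore uncertain. The table has 38483 genes, of which 36639 (95.2%) took a symbol from the annotation and 1844 did not, and the latter held 0.291% to 0.536% of each library's counts. The annotation shared 36723 identifiers with the table, of which 36625 were on the same chromosome and 36550 overlapped in position. All columns were assigned to a library from the labels, with 0 left over.

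Total counts ranged from 47206930 to 127883025 per library. A count of 0 allows up to 3 counts, or 0.0222 to 0.0677 CPM depending on the library. Mitochondrial genes took 1.11% to 2.78% of counts and protein-coding genes 95.5% to 97.3%. Between 18006 and 24207 genes had at least 1 count, and 9546 had none in any library. Pearson correlations of log2 CPM between replicates ranged from 0.974 to 0.991, and chi-square over degrees of freedom between replicates from 43.6 to 165, so none of these 6 pairs within groups were copies.

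Counts were analyzed in R 4.3.3 with edgeR 4.0.16, using TMM scaling (factors 0.805 to 1.25), filterByExpr with a minimum count of 10, and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The 9 marrow libraries were fitted together with 1 term per population for the 3 marrow comparisons and for a test of any difference among the 4 populations. Blood and marrow monocytes were compared in the 7 monocyte libraries with terms for subset and tissue. The difference between tissues in the Ly6Clow over Ly6Chi fold was tested over all 11 libraries, a fit in which the lone blood libraries are assumed to vary like the marrow groups. Group levels are means of TMM-scaled CPM. The ratio of the 2 blood libraries used a pseudocount of 0.1 CPM, and their exact Poisson intervals are at 95%. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

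Groups, comparisons, 30 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule names, per comparison, the 8 largest rises and the 8 largest falls among called genes with a symbol of a known gene, a mean of at least 20 CPM in the higher group and no overlap between the libraries of both groups (within each subset for blood against marrow). It also names up to 4 members per list with the smallest p-values, and in every comparison Nr4a1, Klf2, Irf8, Kit, Csf1r, Ly6c1, Ly6c2, Flt3 and Itgax. Which of these genes serve as examples in the text was chosen after their values were seen, as were Ly6g in cMoP and MDP, Mcpt8 and Ngp per library. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation of 0.01 and with an estimated correlation. With the estimated correlation, 0 of 15 calls held in cMoP against MDP, 0 of 22 in Ly6Chi monocytes against cMoP, 1 of 22 in Ly6Clow against Ly6Chi and 0 of 18 in blood against marrow. This setting also lowers the degrees of freedom of camera's test to the residual ones of the fit. The lost calls therefore cannot be put down to correlation between genes alone. The fry test, which asks whether a list's genes move on balance one way and compares them with no other genes, called 15, 26, 25 and 8 lists in the same order. The median, mean and test of a list differed in sign in 12 of 120 list tests, of which 0 were called; among them, secondary granule genes in marrow Ly6Clow over Ly6Chi cells had a median of 0.53, a mean of -0.24 and a test direction of down.

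Alternatives were size factors in the manner of DESeq2, upper-quartile scaling, no filter or a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a minimum change of 2-fold, a test against 1.5-fold, a replicate block, fits of fewer or more libraries and leaving out each library in turn. For lists they also included a prior count of 0.5. The code was tested on simulated data made from the libraries' own counts in which some genes were changed by known folds. In cMoP against MDP edgeR recovered 5 of 67 genes changed 1.5-fold, 39 of 67 changed 2-fold and 40 of 66 changed 4-fold. In Ly6Chi monocytes against cMoP edgeR recovered 7 of 67 genes changed 1.5-fold, 38 of 67 changed 2-fold and 53 of 66 changed 4-fold. In Ly6Clow against Ly6Chi edgeR recovered 11 of 67 genes changed 1.5-fold, 34 of 67 changed 2-fold and 47 of 66 changed 4-fold, and in blood against marrow edgeR recovered 1 of 67 genes changed 1.5-fold, 26 of 67 changed 2-fold and 39 of 66 changed 4-fold. Of the 4-fold changes at 20 CPM or more, 24 of 24, 31 of 31, 27 of 27 and 29 of 31 were recovered, and 0 genes were called in the wrong direction. Unchanged genes made up 14.3%, 11.7%, 10.7% and 7.04% of the calls, above the nominal 5%. The requirement first set, on the recovery of 4-fold changes over all genes, was missed in cMoP against MDP (60.6%), and the requirement on genes at 20 CPM or more was set after that result. Neither requirement on recovery was applied to blood against marrow, where 59.1% of the 4-fold changes were recovered. The list that was changed was called in 4 of 4 comparisons, and 0 of 30 unchanged lists were called in any. The simulated genes were drawn independently of each other, so this cannot show how often lists of correlated genes are called falsely.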

Results

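RNA sequencing was done on monocytes and their progenitors sorted from the bone marrow and blood of 10-week-old male C57BL/6 mice. Monocyte-dendritic cell progenitors (MDP) were sorted as lineage-negative CD117+ CD115+ Ly6Clow marrow cells, and common monocyte progenitors (cMoP) as the Ly6Chi cells of the same CD117+ CD115+ gate. Marrow monocytes were lineage-negative CD117- CD115+ and were split into Ly6Chi (classical) and Ly6Clow (patrolling) cells. Blood monocytes of both kinds were lineage-negative and CD115+, and their labelled gate does not mention CD117. There were 2 libraries of MDP, 2 of cMoP, 3 of marrow Ly6Chi monocytes and 2 of marrow Ly6Clow monocytes, with 1 library each of blood Ly6Chi and blood Ly6Clow monocytes. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Total counts were 105188332 and 108439404 in MDP, 102458814 and 88869971 in cMoP, and 127883025, 93571914 and 93759705 in marrow Ly6Chi. They were 47206930 and 86793847 in marrow Ly6Clow, 98899596 in blood Ly6Chi and 98531655 in blood Ly6Clow. Levels are CPM, counts scaled to library size by TMM, with the SD between libraries, and fold changes are log2 values with their SE.

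The study's title concerns an enhancer of Nr4a1 and Ly6Clow monocytes. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101266846 to 101274792 on mm10) encodes an orphan nuclear receptor needed for Ly6Clow monocytes. It was measured at 4.73 and 6.08 CPM in MDP, 5.84 and 5.11 in cMoP, 59.5, 68.3 and 106 in marrow Ly6Chi, 979.9 and 778 in marrow Ly6Clow, 563 in blood Ly6Chi and 2387 in blood Ly6Clow. Across the 4 marrow populations, 12898 of 17703 tested genes (72.9%) differed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The leading component of log2 CPM, with 55.6% of the variance, placed the 4 progenitor libraries between -147 and -124 and the 7 monocyte libraries between 25 and 131. The other, with 18.5%, separated the 4 Ly6Chi libraries (32.2 to 79.3) from the 3 Ly6Clow libraries (-81.7 to -44.3).

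**Figure D1:**
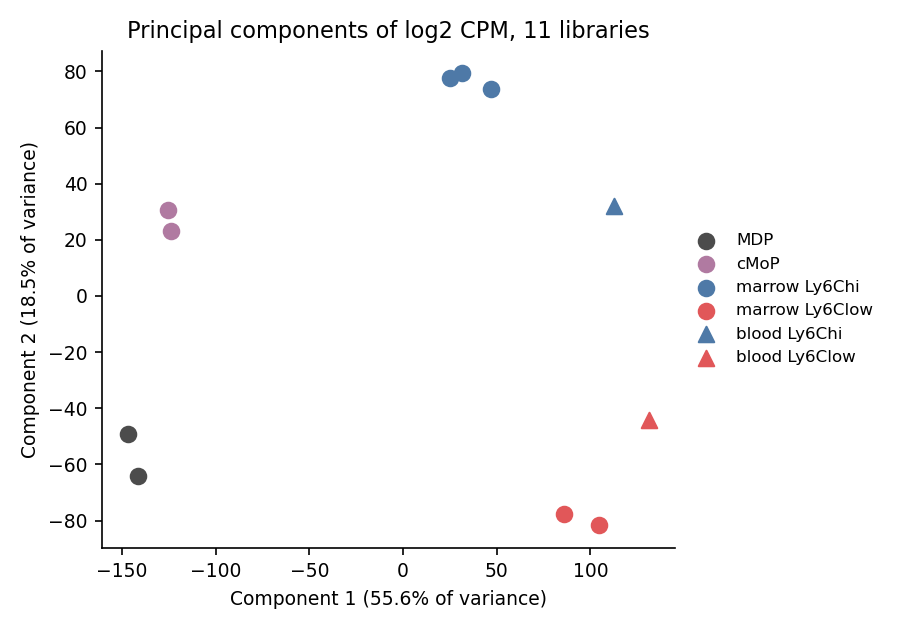
Principal components of log2 CPM in 11 libraries, with component 1 on the horizontal axis (55.6% of the variance) and component 2 on the vertical axis (18.5%). Each point is 1 library, circles are marrow and triangles are blood, and the 4 progenitor libraries lie at the far left.

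**Figure D2:**
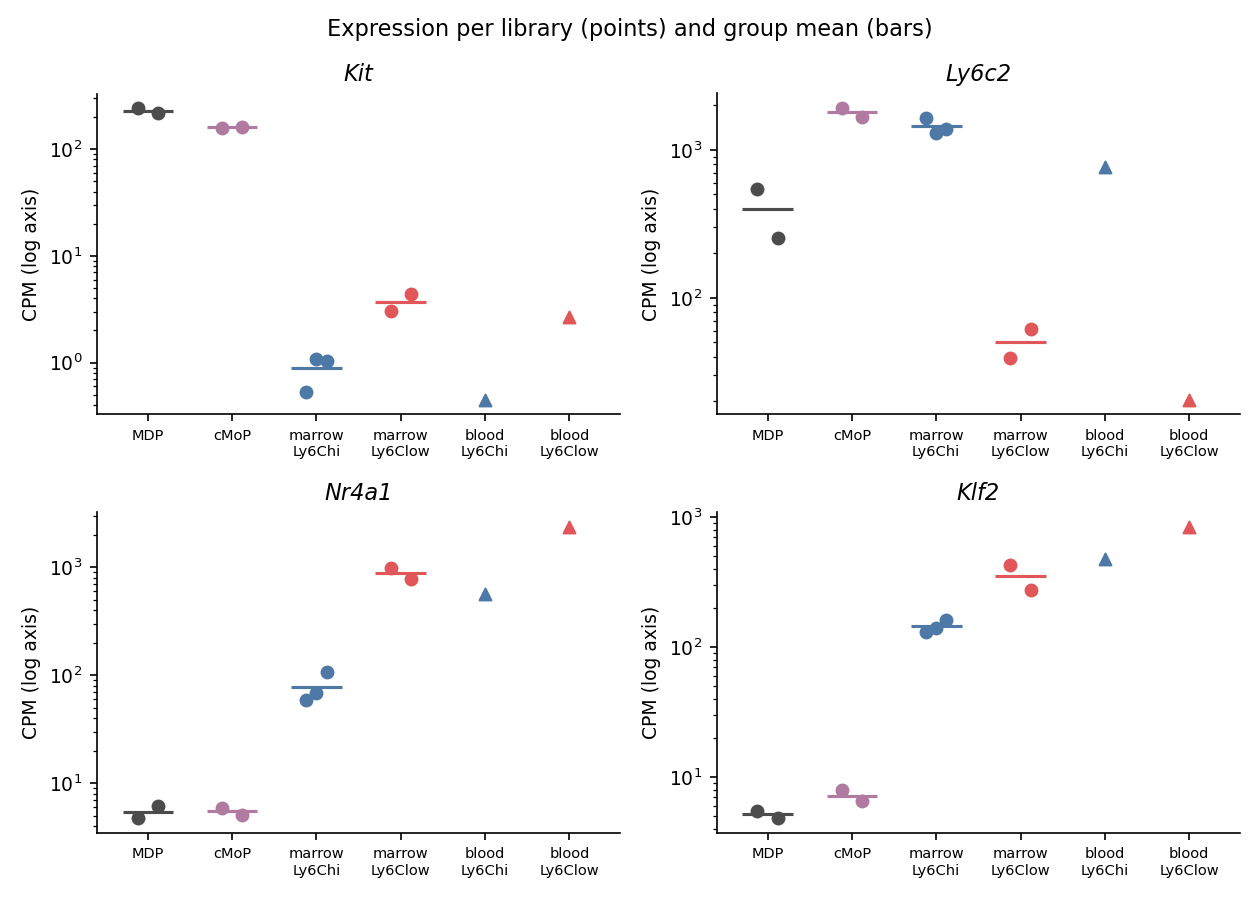
Kit, Ly6c2, Nr4a1 and Klf2 in each library, in CPM on a log axis, with points for libraries and bars for group means. Kit was 229.6 ± 17.8 CPM in MDP and 0.883 ± 0.308 in marrow Ly6Chi monocytes (SD, n = 2 and 3), while Nr4a1 went from 5.40 ± 0.958 in MDP to 879 ± 143 in marrow Ly6Clow monocytes (SD, n = 2 each).

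The comparison of cMoP with MDP asks what changes between these progenitors before CD117 is lost. Most granule genes and Ly6Chi monocyte markers were higher in cMoP, and most dendritic cell and MHC class II genes were lower. Camera called 15 lists, and 0 with an estimated correlation between genes. Chil3, a secreted chitinase-like protein, was 401 ± 85.5 CPM in cMoP and 16.7 ± 9.33 in MDP (log2 fold change 4.59 ± 0.48, adjusted p = 0.00017 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 each). The antimicrobial peptide gene Camp rose from 13.7 ± 7.28 to 272 ± 37.0 CPM (log2 4.31, adjusted p = 0.00021). Dntt, the template-independent DNA polymerase of lymphoid precursors, fell from 146 ± 93.6 to 0.395 ± 0.143 CPM (log2 -8.54, adjusted p = 2.0e-05). Flt3, the receptor for FLT3 ligand, fell from 348 ± 143 to 13.3 ± 6.32 CPM (log2 -4.71, adjusted p = 0.00021). The other largest rises were Fcnb, S100a9, Itgb2l, Ngp, Cd177 and S100a8, with log2 values of 4.55, 4.04, 3.97, 3.91, 3.90 and 3.82. The other largest falls were Ly6d, Siglech, Epha2, Cmah, Ephb2 and Snn, with log2 values of -6.24, -4.86, -4.79, -4.61, -4.59 and -4.58.

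Among secondary granule and neutrophil genes, 12 of 16 tested members rose, 0 fell and 4 did not pass. Here 14 rose and 0 fell adjusted over the list alone, with camera adjusted p = 3.0e-09, and adjusted p = 0.25 with an estimated correlation. Lcn2, a siderophore-binding protein, rose by a log2 value of 3.66 (adjusted p = 0.00012). These genes are also markers of neutrophils, and Ly6g, a neutrophil surface gene used for lineage exclusion, was at 1.25 and 0.942 CPM in cMoP and 0.213 and 0.104 in MDP. Primary granule genes followed the same direction: 11 of 16 tested members rose, 0 fell and 5 did not pass, with Prtn3, a serine protease of azurophilic granules, at 2833 ± 433 against 1026 ± 371 CPM (log2 1.46, adjusted p = 0.0027). When adjusted over the list alone, 12 rose and 0 fell, with camera adjusted p = 6.7e-06, and adjusted p = 0.37 with an estimated correlation. Of the Ly6Chi monocyte markers, 12 of the 20 tested rose, 2 fell and 6 did not pass, led by Fn1 (log2 3.34, adjusted p = 6.1e-06) and Lyz2 (log2 2.91, adjusted p = 3.2e-05). Counts adjusted over the list alone were 14 up and 2 down, with camera adjusted p = 1.8e-06, and adjusted p = 0.25 with an estimated correlation. Among pattern recognition receptors 18 of 26 tested members rose, 2 fell and 6 did not pass, and Tlr8 rose (log2 2.74) where Tlr3 fell (log2 -4.63). With p-values adjusted over the list alone, 18 rose and 3 fell, with camera adjusted p = 5.1e-06, and adjusted p = 0.38 with an estimated correlation. Lysosome genes had 19 of 30 tested members that rose, 2 that fell and 9 that did not pass, among them Ctsc (log2 1.77) and Lamp1 (log2 1.14). Adjusted over the list alone, 20 rose and 2 fell, with camera adjusted p = 4.3e-06, and adjusted p = 0.25 with an estimated correlation.

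Of the plasmacytoid dendritic cell genes, 12 of the 13 tested fell, 0 rose and 1 did not pass, including Cox6a2 (log2 -5.60) and Runx2 (log2 -2.66). Of these members, 0 rose and 12 fell adjusted over the list alone, with camera adjusted p = 4.6e-10, and adjusted p = 0.25 with an estimated correlation. Conventional dendritic cell genes showed the same direction: 11 of 18 tested members fell, 2 rose and 5 did not pass, with Ccr7 at a log2 value of -5.66 and Zbtb46 at -3.25, while Mgl2 rose (log2 2.35). In this list 3 rose and 11 fell adjusted over the list alone, with camera adjusted p = 6.7e-06, and adjusted p = 0.25 with an estimated correlation. Of the genes of MHC class II presentation, 7 of the 13 tested fell, 1 rose and 5 did not pass, with H2-Aa at 9.86 ± 1.56 CPM in cMoP and 156 ± 20.6 in MDP. For these genes, 1 rose and 7 fell adjusted over the list alone, with camera adjusted p = 9.4e-06, and adjusted p = 0.25 with an estimated correlation. Progenitor transcription factors split: 9 of 19 tested members fell, 3 rose and 7 did not pass, with Sox4 (log2 -2.22) and Meis1 (log2 -1.96) among those that fell. Among them, 3 rose and 13 fell adjusted over the list alone, with camera adjusted p = 3.9e-05, and adjusted p = 0.25 with an estimated correlation. Markers of other cell types moved with these groups, in part. Among B cell and plasma cell genes 5 of 18 tested members fell, 0 rose and 13 did not pass (camera adjusted p = 0.00039, and adjusted p = 0.33 with an estimated correlation), and among T cell and NK cell genes 6 of 22 tested members fell, 0 rose and 16 did not pass (camera adjusted p = 0.0083, and adjusted p = 0.51 with an estimated correlation). In the basophil, mast cell and eosinophil list 4 of 17 tested members fell, 1 rose and 12 did not pass (adjusted over the list alone, 1 rose and 7 fell; camera adjusted p = 0.011, and adjusted p = 0.66 with an estimated correlation), a list call lost without MDP library 1 (adjusted p = 0.29) or cMoP library 1 (0.061). In the megakaryocyte and platelet list 3 of 14 tested members fell, 0 rose and 11 did not pass (adjusted over the list alone, 1 rose and 5 fell; camera adjusted p = 0.045, and adjusted p = 0.69 with an estimated correlation), a list call lost without MDP 1, cMoP 1, Ly6Chi 2, Ly6Clow 1 or Ly6Clow 2 (adjusted p = 0.063 to 0.48). Myeloid transcription factors went both ways: 10 of 33 tested members rose, 5 fell and 18 did not pass (adjusted over the list alone, 12 rose and 6 fell; camera adjusted p = 0.29, and adjusted p = 0.88 with an estimated correlation). Few cell cycle genes moved: 1 of 50 tested members rose, 3 fell and 46 did not pass (adjusted over the list alone, 1 rose and 2 fell; camera adjusted p = 0.68, and adjusted p = 0.96 with an estimated correlation). Of the ribosome biogenesis genes, 29 of 30 did not pass (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.87, and adjusted p = 0.96 with an estimated correlation).

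Of the gate genes, Ly6c2 was 1801 ± 167 CPM in cMoP and 399 ± 202 in MDP (log2 fold change 2.17 ± 0.32, adjusted p = 0.00097), and Kit, which encodes CD117, was 159 ± 1.78 against 229.6 ± 17.8 CPM (log2 fold change -0.53 ± 0.23, adjusted p = 0.16). Ly6c1 and Ly6c2 are near-identical copies, so their reads may be split between them. Csf1r, which encodes CD115, rose by a log2 value of 0.53 (adjusted p = 0.011), a call lost without MDP library 2 (adjusted p = 0.087) or cMoP library 1 (0.10). Itgax, which encodes CD11c, fell from 68.4 ± 27.7 to 6.28 ± 4.28 CPM (log2 -3.45, adjusted p = 0.00061). The values were 5.48 ± 0.520 against 5.40 ± 0.958 CPM for Nr4a1 (log2 fold change 0.02 ± 0.26, adjusted p = 0.98), 7.23 ± 0.973 against 5.19 ± 0.492 for Klf2 (adjusted p = 0.14) and 961 ± 75.8 against 1173 ± 146 for Irf8 (adjusted p = 0.17). In all, 1592 of 17703 genes were higher and 1468 lower in cMoP, a split of 52.0% higher that became 41.7% with upper-quartile scaling. The counts fell to 668 and 635 without MDP library 2, to 772 and 644 without cMoP library 1 and to 1029 and 869 without cMoP library 2.

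Marrow Ly6Chi monocytes were compared with cMoP, the step at which CD117 is lost. Most progenitor transcription factors and primary granule genes fell, and most interferon, pattern recognition and antigen presentation genes rose. There were 22 lists called by camera, and 0 with an estimated correlation between genes. Kit was 0.883 ± 0.308 CPM in Ly6Chi monocytes (n = 3) and 159 ± 1.78 in cMoP (n = 2), with log2 fold change -7.52 ± 0.27, adjusted p = 2.9e-08 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Mpo, the myeloperoxidase of azurophilic granules, fell from 12036 ± 2101 to 161 ± 37.9 CPM (log2 -6.22, adjusted p = 7.0e-08). Vcan, a matrix proteoglycan, rose from 7.55 ± 1.96 to 384 ± 84.0 CPM (log2 5.67, adjusted p = 1.0e-07). Nr4a1 rose from 5.48 ± 0.520 to 78.0 ± 24.8 CPM (log2 3.84, adjusted p = 1.1e-06) and Klf2 from 7.23 ± 0.973 to 145 ± 15.5 (log2 4.32, adjusted p = 1.2e-07). The other largest rises were Ms4a8a, Atf3, Siglec1, Ifit3, Prr5l, Rtp4 and Slfn1, with log2 values of 5.93, 5.76, 5.73, 5.62, 5.59, 5.57 and 5.56. The other largest falls were Prom1, Vegfa, Gfi1, Prss57, Serpine2 and Nkg7, with log2 values of -7.07, -6.85, -6.85, -6.38, -6.19 and -6.17.

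Among interferon-stimulated genes 29 of 30 tested members rose, 1 fell and 0 did not pass, with Irf7, a transcription factor of the interferon response, at 188 ± 12.2 against 5.55 ± 0.402 CPM. Here 29 rose and 1 fell adjusted over the list alone, with camera adjusted p = 1.4e-15, and adjusted p = 0.14 with an estimated correlation. For pattern recognition receptors 26 of 26 tested members rose, 0 fell and 0 did not pass, with Clec4a1 at a log2 value of 5.20 and Nod2 at 4.38. When adjusted over the list alone, 26 rose and 0 fell, with camera adjusted p = 7.9e-11, and adjusted p = 0.14 with an estimated correlation. Myeloid transcription factors had 27 of 33 tested members that rose, 3 that fell and 3 that did not pass, including Irf4 (log2 4.95) and Bcl6 (log2 2.89). Counts adjusted over the list alone were 27 up and 3 down, with camera adjusted p = 1.7e-08, and adjusted p = 0.14 with an estimated correlation. Of the MHC class II presentation genes, 10 of the 13 tested rose, 1 fell and 2 did not pass, and Cd74, the invariant chain, went from 26.4 ± 0.681 to 538 ± 40.1 CPM. With p-values adjusted over the list alone, 10 rose and 1 fell, with camera adjusted p = 4.9e-05, and adjusted p = 0.14 with an estimated correlation. Conventional dendritic cell genes had 10 of 18 tested members that rose, 2 that fell and 6 that did not pass (adjusted over the list alone, 11 rose and 3 fell; camera adjusted p = 0.016, and adjusted p = 0.37 with an estimated correlation). Lysosome genes rose in 24 of 30 cases and fell in 3, with Cd68 up (log2 2.99) and Cd63 down (log2 -5.25). Adjusted over the list alone, 25 rose and 3 fell, with camera adjusted p = 2.2e-07, and adjusted p = 0.14 with an estimated correlation. Cell cycle inhibitors and quiescence genes had 13 of 15 tested members that rose, 0 that fell and 2 that did not pass, among them Btg2 (log2 2.88) and Cdkn1a (log2 1.99). Of these members, 13 rose and 0 fell adjusted over the list alone, with camera adjusted p = 5.4e-05, and adjusted p = 0.13 with an estimated correlation. Of the Nr4a family and Krueppel-like factors, 7 of the 9 tested rose, 1 fell and 1 did not pass. In this list 7 rose and 1 fell adjusted over the list alone, with camera adjusted p = 0.0012, and adjusted p = 0.14 with an estimated correlation. Of the Ly6Clow monocyte markers, 16 of the 23 tested rose, 4 fell and 3 did not pass, including S1pr5 (log2 4.46) and Ace (log2 4.32). For these genes, 16 rose and 4 fell adjusted over the list alone, with camera adjusted p = 7.7e-05, and adjusted p = 0.13 with an estimated correlation.

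Primary granule genes went the other way: 15 of 16 tested members fell, 0 rose and 1 did not pass, with Ctsg at 94.7 ± 14.7 CPM against 1761 ± 119 in cMoP. Among them, 0 rose and 15 fell adjusted over the list alone, with camera adjusted p = 8.3e-09, and adjusted p = 0.14 with an estimated correlation. Of the ribosome biogenesis genes, 29 of the 30 tested fell, 0 rose and 1 did not pass, Dkc1 by a log2 value of -2.12. Here 0 rose and 29 fell adjusted over the list alone, with camera adjusted p = 5.9e-12, and adjusted p = 0.14 with an estimated correlation. Cell cycle genes had 26 of 50 tested members that fell, 2 that rose and 22 that did not pass, with Ccnd2 (log2 -5.57) and Cdk6 (log2 -3.11) falling and E2f2 rising (log2 2.07). When adjusted over the list alone, 2 rose and 26 fell, with camera adjusted p = 2.7e-05, and adjusted p = 0.53 with an estimated correlation. Progenitor transcription factors fell in 14 of 19 cases with none rising, among them Erg (log2 -5.83) and Myb (log2 -3.91). Counts adjusted over the list alone were 0 up and 17 down, with camera adjusted p = 1.1e-05, and adjusted p = 0.14 with an estimated correlation. Progenitor surface genes went both ways: 5 of 16 tested members rose, 5 fell and 6 did not pass (adjusted over the list alone, 5 rose and 5 fell; camera adjusted p = 0.54, and adjusted p = 0.66 with an estimated correlation). Basophil, mast cell and eosinophil genes, which mark other cells, moved with them: 11 of 17 tested members fell, 0 rose and 6 did not pass, with Hdc at 2.54 ± 0.719 against 98.4 ± 6.90 CPM. With p-values adjusted over the list alone, 0 rose and 12 fell, with camera adjusted p = 0.00099, and adjusted p = 0.42 with an estimated correlation. Neutrophil granule genes fell in 10 of 16 cases and rose in 3, with Camp down (log2 -5.28) and Mmp8 up (log2 4.34). Adjusted over the list alone, 3 rose and 10 fell, with camera adjusted p = 0.059, and adjusted p = 0.64 with an estimated correlation. Macrophage genes rose in 12 of 20 cases and fell in 2. Of these members, 12 rose and 2 fell adjusted over the list alone, with camera adjusted p = 0.0037, and adjusted p = 0.44 with an estimated correlation. In the T cell and NK cell list 1 of 22 tested members rose, 0 fell and 21 did not pass (adjusted over the list alone, 1 rose and 0 fell; camera adjusted p = 0.92, and adjusted p = 0.97 with an estimated correlation). Among gate genes, Csf1r rose (log2 1.56), Flt3 rose (log2 1.71, adjusted p = 0.0072, or 0.074 without cMoP library 1) and Ly6c2 was at 1449 ± 176 against 1801 ± 167 CPM (adjusted p = 0.37). Irf8 fell by 0.59 on the log2 scale (adjusted p = 0.0016), and Itgax was 4.06 ± 1.22 against 6.28 ± 4.28 CPM (adjusted p = 0.22). In all, 4587 genes were higher and 4649 lower in Ly6Chi monocytes, of which 2515 and 2449 changed at least 2-fold.

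Marrow Ly6Clow monocytes were compared with marrow Ly6Chi monocytes, the pair on which the study's title bears. Nr4a1, C1q, Ly6Clow marker and most antigen presentation genes were higher in Ly6Clow cells, and most cell cycle, primary granule and classical monocyte genes were lower. Of the 22 lists that camera called, the Ly6Clow markers alone were called with an estimated correlation between genes. Nr4a1 was 879 ± 143 CPM in Ly6Clow (n = 2) and 78.0 ± 24.8 in Ly6Chi monocytes (n = 3), with log2 fold change 3.50 ± 0.23, adjusted p = 1.5e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cd300e, an activating receptor of monocytes, rose from 0.555 ± 0.110 to 438 ± 22.8 CPM (log2 9.63, adjusted p = 1.8e-09). C1qa, a chain of complement component C1q, rose from 0.513 ± 0.142 to 188 ± 67.3 CPM (log2 8.55, adjusted p = 6.9e-08). Ly6c2, the gate gene, fell from 1449 ± 176 to 50.7 ± 15.7 CPM (log2 -4.83, adjusted p = 2.9e-06), and Vcan from 384 ± 84.0 to 1.91 ± 0.502 (log2 -7.61, adjusted p = 6.5e-08). The other largest rises were Atp6v0d2, Adrb1, Asb2, Cadm1, Lilra5 and C1qc, with log2 values of 9.50, 8.77, 8.05, 7.92, 7.74 and 7.70. The other largest falls were Hal, Chil3, Fn1, Mmp8, Cd177 and Padi4, with log2 values of -6.29, -5.88, -5.49, -5.21, -4.85 and -4.71.

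All 23 Ly6Clow monocyte markers rose, with Slc12a2, Cd274, Tgfbr3 and Eno3 at log2 values of 5.54, 5.22, 6.76 and 4.97. In this list 23 rose and 0 fell adjusted over the list alone, with camera adjusted p = 5.2e-20, and adjusted p = 0.0098 with an estimated correlation, the 1 call among the 22 lists called here that was kept. The list holds genes chosen beforehand as markers of Ly6Clow monocytes, so this call checks the sort and is no separate finding. Itgax rose from 4.06 ± 1.22 to 445 ± 12.7 CPM (log2 6.79, adjusted p = 1.6e-06). MHC class II presentation genes had 11 of 13 tested members that rose, 0 that fell and 2 that did not pass, with H2-Aa at 4419 ± 356 against 144 ± 30.2 CPM, Cd74 at a log2 value of 4.25 and H2-Eb1 at 5.82. For these genes, 11 rose and 0 fell adjusted over the list alone, with camera adjusted p = 2.8e-08, and adjusted p = 0.15 with an estimated correlation. Lipid handling and cholesterol efflux genes had 12 of 25 tested members that rose, 2 that fell and 11 that did not pass, among them the scavenger receptor Cd36 (log2 6.08), Pparg (log2 5.33) and Pltp (log2 4.19). Among them, 13 rose and 2 fell adjusted over the list alone, with camera adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation. Of the chemokine receptor and migration genes, 17 of the 31 tested rose, 5 fell and 9 did not pass, with the sphingosine phosphate receptor S1pr5 at 387 ± 55.4 against 14.4 ± 1.63 CPM. Here 18 rose and 5 fell adjusted over the list alone, with camera adjusted p = 0.0015, and adjusted p = 0.15 with an estimated correlation. Among Fc receptor and complement genes 14 of 20 tested members rose, 4 fell and 2 did not pass, with log2 values from -3.27 to 8.55 (adjusted over the list alone, 14 rose and 4 fell; camera adjusted p = 0.00040, and adjusted p = 0.21 with an estimated correlation). Among immediate-early genes 15 of 31 tested members rose, 1 fell and 15 did not pass, with Dusp5 (log2 4.82) and Il1b (log2 4.62). When adjusted over the list alone, 15 rose and 1 fell, with camera adjusted p = 0.00038, and adjusted p = 0.39 with an estimated correlation. Myeloid transcription factors had 16 of 33 tested members that rose, 5 that fell and 12 that did not pass, including Hes1 (log2 5.12), Nr1h3 (log2 3.83) and Bcl6 (log2 2.16). Counts adjusted over the list alone were 17 up and 5 down, with camera adjusted p = 0.0017, and adjusted p = 0.36 with an estimated correlation. Without Ly6Clow library 1 the camera adjusted p of this list was 0.065.

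Markers of other cell types were also higher in Ly6Clow cells. Of the macrophage genes, 19 of the 20 tested rose, 0 fell and 1 did not pass, with C1qb at 232 ± 54.2 against 1.51 ± 0.421 CPM and the mannose receptor Mrc1 at 316 ± 0.289 against 27.7 ± 1.37. With p-values adjusted over the list alone, 19 rose and 0 fell, with camera adjusted p = 5.2e-12, and adjusted p = 0.21 with an estimated correlation. Conventional dendritic cell genes had 12 of 18 tested members that rose, 3 that fell and 3 that did not pass, with Cd209a at 695 ± 12.7 against 40.2 ± 7.16 CPM and Cd83, Mgl2 and Clec10a at log2 values of 6.49, 5.43 and 2.58. Adjusted over the list alone, 12 rose and 3 fell, with camera adjusted p = 3.7e-05, and adjusted p = 0.21 with an estimated correlation. Of the plasmacytoid dendritic cell genes, 10 of the 13 tested rose, 1 fell and 2 did not pass, among them Spib (log2 4.58) and Runx2 (log2 2.69). Of these members, 10 rose and 1 fell adjusted over the list alone, with camera adjusted p = 7.5e-05, and adjusted p = 0.30 with an estimated correlation. B cell and plasma cell genes had 13 of 18 tested members that rose, 0 that fell and 5 that did not pass, with Cd22 at 38.1 ± 1.32 against 1.83 ± 0.763 CPM and Cd79a at 2.75 ± 0.218 against 0.602 ± 0.0777. In this list 14 rose and 0 fell adjusted over the list alone, with camera adjusted p = 1.0e-05, and adjusted p = 0.21 with an estimated correlation. T cell and NK cell genes had 14 of 22 tested members that rose, 0 that fell and 8 that did not pass, with Cd4 (log2 6.56) and Klrd1 (log2 5.84). For these genes, 14 rose and 0 fell adjusted over the list alone, with camera adjusted p = 1.2e-05, and adjusted p = 0.22 with an estimated correlation. Among erythroid genes 13 of 16 tested members rose, 0 fell and 3 did not pass, with Hbb-bs at 32.0 ± 8.58 against 4.2 ± 2.49 CPM and Alas2 at 3.43 ± 0.479 against 0.486 ± 0.0391. Among them, 14 rose and 0 fell adjusted over the list alone, with camera adjusted p = 0.00017, and adjusted p = 0.36 with an estimated correlation. In the basophil, mast cell and eosinophil list 7 of 17 tested members rose, 0 fell and 10 did not pass (adjusted over the list alone, 7 rose and 0 fell; camera adjusted p = 0.0031, and adjusted p = 0.43 with an estimated correlation), and among megakaryocyte and platelet genes 6 of 14 tested members rose, 1 fell and 7 did not pass (adjusted over the list alone, 6 rose and 1 fell; camera adjusted p = 0.0077, and adjusted p = 0.43 with an estimated correlation).

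Cell cycle genes were lower in Ly6Clow cells: 47 of 50 tested members fell, 3 rose and 0 did not pass, with Tyms (log2 -2.68), Ccne1 (log2 -2.74) and Cdc6 (log2 -2.49) among those that fell. The cyclin gene Ccnd1 rose from 2.64 ± 0.764 to 98.8 ± 5.30 CPM. Here 3 rose and 47 fell adjusted over the list alone, with camera adjusted p = 2.4e-13, and adjusted p = 0.31 with an estimated correlation. Of the oxidative phosphorylation genes, 28 of the 33 tested fell, 0 rose and 5 did not pass, with small changes such as those of Uqcrfs1 (log2 -0.77) and Sdhc (log2 -0.67). When adjusted over the list alone, 0 rose and 30 fell, with camera adjusted p = 3.2e-08, and adjusted p = 0.21 with an estimated correlation. Ly6Chi monocyte markers had 15 of 20 tested members that fell, 3 that rose and 2 that did not pass. Counts adjusted over the list alone were 3 up and 15 down, with camera adjusted p = 1.2e-05, and adjusted p = 0.22 with an estimated correlation. Primary granule genes had 12 of 16 tested members that fell, 1 that rose and 3 that did not pass, with Ctsg (log2 -3.32) and Prtn3 (log2 -3.76). With p-values adjusted over the list alone, 1 rose and 13 fell, with camera adjusted p = 3.7e-05, and adjusted p = 0.31 with an estimated correlation. Secondary granule and neutrophil genes went both ways: 5 of 16 tested members rose, 5 fell and 6 did not pass (adjusted over the list alone, 6 rose and 6 fell; camera adjusted p = 0.64, and adjusted p = 0.90 with an estimated correlation). Of the interferon-stimulated genes, 14 of the 30 tested fell, 0 rose and 16 did not pass, with Cmpk2 at 37.6 ± 3.13 against 125 ± 20.3 CPM and Oasl1 at 6.54 ± 1.55 against 13.1 ± 1.48. Adjusted over the list alone, 0 rose and 15 fell, with camera adjusted p = 0.0043, and adjusted p = 0.50 with an estimated correlation. Klf2 rose (log2 1.29, adjusted p = 0.00023), as did Csf1r (log2 1.26), Flt3 (log2 2.01) and Kit (log2 2.13, to 3.73 ± 0.927 CPM), while Irf8 (log2 -0.79) and Ly6c1 (log2 -4.10) fell. In all, 3319 genes were higher and 3324 lower in Ly6Clow cells, and 2014 and 1249 of them changed at least 2-fold.

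**Figure D3:**
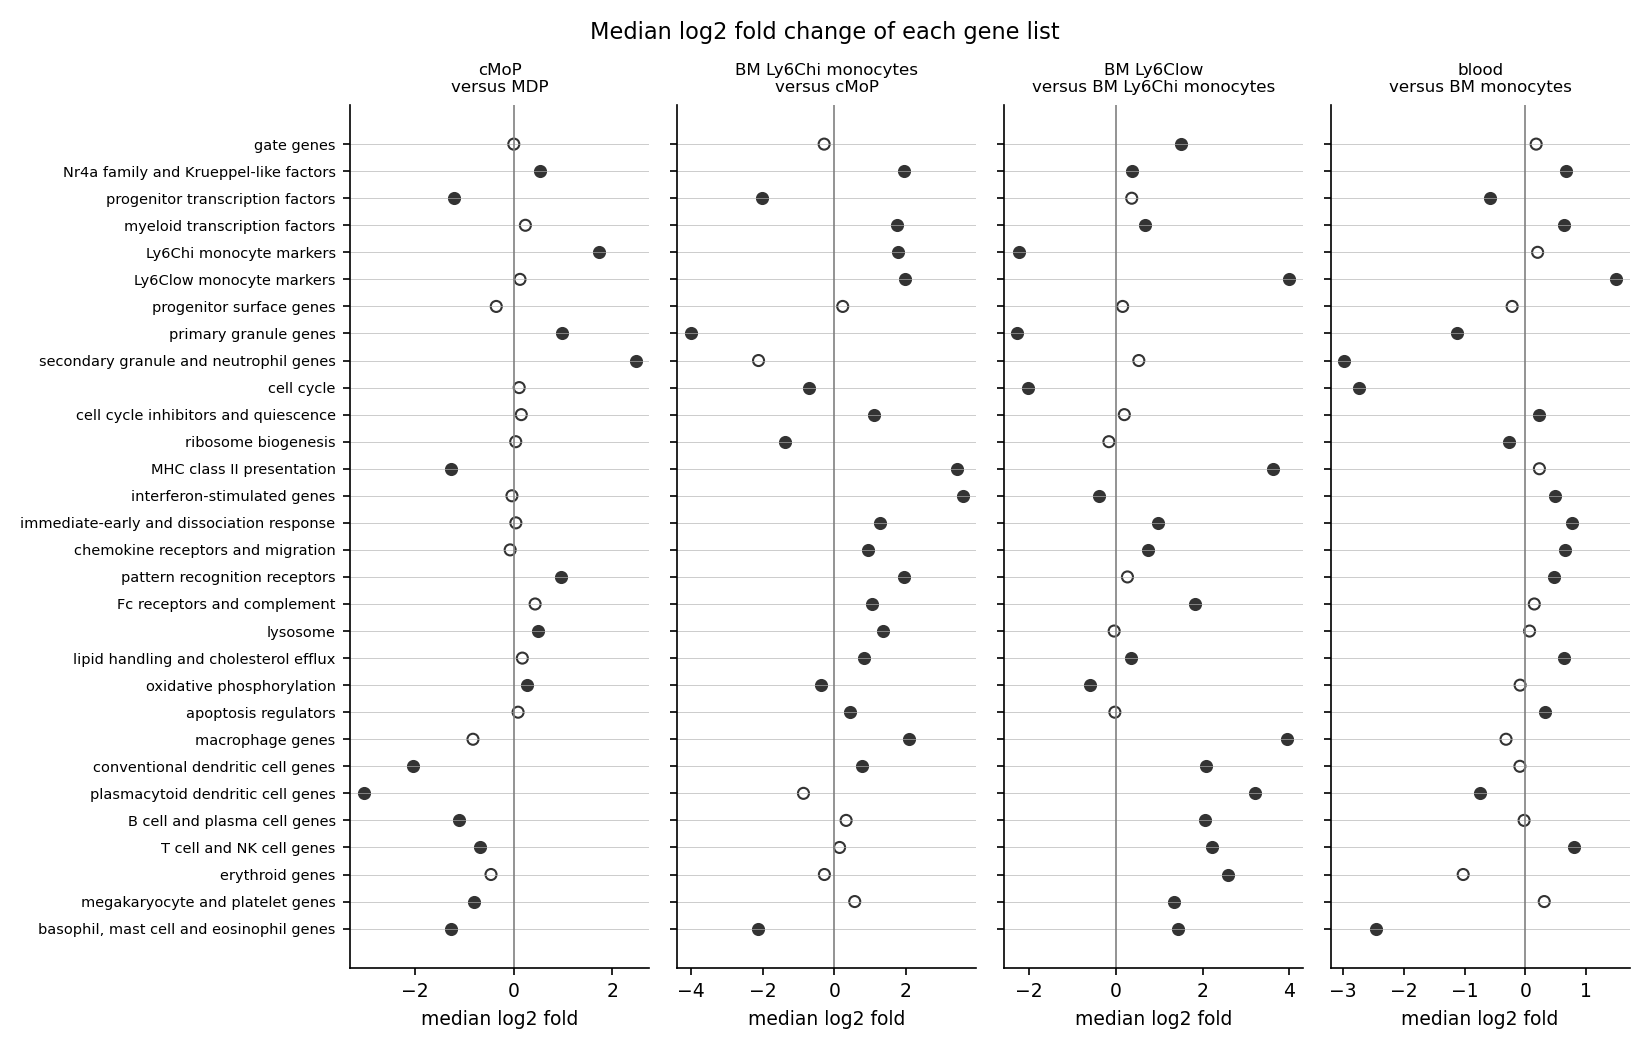
Median log2 fold change of each of the 30 gene lists in the 4 tested comparisons, with 1 row per list, the median on the horizontal axis and a filled point where camera's adjusted p is under 0.05. The Ly6Clow monocyte markers have a median of 4.0 in marrow Ly6Clow over Ly6Chi cells and 1.5 in blood over marrow.

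Blood monocytes were compared with marrow monocytes with a term for subset, with 2 blood libraries against 5 marrow libraries. The fit gives both subsets 1 shared tissue fold. Where the subsets differ in that fold, the difference goes into the residual spread, and so into the SE and p-value. Nr4a1, most Ly6Clow markers and part of the immediate response genes were higher in blood, and part of the cell cycle and neutrophil granule genes were lower. With an estimated correlation between genes, camera's 18 list calls became 0. Both blood libraries have number 1, so a difference that goes with the number is not separated from the tissue without a replicate block. A handling difference between blood and marrow samples also goes with the tissue. The fit cannot separate it from a tissue difference, for Nr4a1 as for any gene. Nr4a1 was at 59.5, 68.3 and 106 CPM in marrow Ly6Chi and 563 in blood Ly6Chi, and at 979.9 and 778 in marrow Ly6Clow and 2387 in blood Ly6Clow (log2 fold change 2.29 ± 0.33, adjusted p = 0.010 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nrarp, a target of Notch signaling, was at 0.153, 0.452 and 0.323 CPM in marrow and 7.01 in blood Ly6Chi, and at 4.43 and 4.41 in marrow and 117 in blood Ly6Clow (log2 4.64, adjusted p = 0.0011). Hes1, another Notch target, was at 0.528, 0.418 and 0.868 CPM in marrow and 21.9 in blood Ly6Chi, and at 24.5 and 17.4 in marrow and 149.7 in blood Ly6Clow (log2 4.24, adjusted p = 0.0052). Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at 110.5, 120.5 and 38.0 CPM in marrow and 1.08 in blood Ly6Chi, and at 16.8 and 23.4 in marrow and 0.984 in blood Ly6Clow (log2 -5.34, adjusted p = 0.0079). The other largest rises were Egr1, Socs3, Tgm3, Il1b, Cd300e and Tppp3, with log2 values of 3.93, 3.84, 3.50, 3.34, 3.06 and 3.02. The other largest falls were Ankle1, Pimreg, Mxd3, Nek2, Kif14, Kif2c and Cenpf, with log2 values of -5.85, -5.84, -5.68, -5.49, -5.32, -5.29 and -5.21.

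Of the Ly6Clow monocyte markers, 19 of the 23 tested rose, 0 fell and 4 did not pass, with Slc12a2, Dusp16 and Itgal at log2 values of 2.57, 2.5 and 1.43. Of these members, 23 rose and 0 fell adjusted over the list alone, with camera adjusted p = 1.2e-15, and adjusted p = 0.30 with an estimated correlation. Immediate-early genes had 12 of 32 tested members that rose, 0 that fell and 20 that did not pass, among them Dusp2 (log2 2.82) and Ppp1r15a (log2 2.31). In this list 19 rose and 1 fell adjusted over the list alone, with camera adjusted p = 6.2e-07, and adjusted p = 0.39 with an estimated correlation. With a replicate block the camera adjusted p was 0.00066. Fos, Jun, Hspa1a and Hspa1b of this list were higher in number 1 than in number 2 libraries in 4 of 4 marrow populations, and did not pass in blood against marrow (adjusted p = 0.15, 0.67, 0.96 and 0.94). Among lipid handling genes 10 of 25 tested members rose, 0 fell and 15 did not pass, with Cd36 (log2 2.59) and Hmgcs1 (log2 1.28). For these genes, 13 rose and 0 fell adjusted over the list alone, with camera adjusted p = 8.6e-06, and adjusted p = 0.30 with an estimated correlation. Chemokine receptor and migration genes had 11 of 31 tested members that rose, 0 that fell and 20 that did not pass, with Cd44 (log2 1.15) and Itga4 (log2 1.02). Among them, 14 rose and 2 fell adjusted over the list alone, with camera adjusted p = 0.0024, and adjusted p = 0.30 with an estimated correlation. Of the Nr4a family and Krueppel-like factors, 4 of the 9 tested rose, 0 fell and 5 did not pass, with Klf2 at a log2 value of 1.53 (adjusted p = 0.0062) and Klf6 at 1.10. Here 6 rose and 0 fell adjusted over the list alone, with camera adjusted p = 0.0016, and adjusted p = 0.30 with an estimated correlation. Cell cycle genes had 24 of 50 tested members that fell, 0 that rose and 26 that did not pass, with E2f8 (log2 -2.70) and Aurkb (log2 -2.78). When adjusted over the list alone, 0 rose and 45 fell, with camera adjusted p = 2.2e-22, and adjusted p = 0.39 with an estimated correlation. Markers of some other cell types fell with them, while T cell and NK cell genes were higher as a list. Of the secondary granule and neutrophil genes, 9 of the 16 tested fell, 1 rose and 6 did not pass, with Ngp at 17.2, 35.7 and 16.3 CPM in marrow and 0.865 in blood Ly6Chi. Counts adjusted over the list alone were 1 up and 10 down, with camera adjusted p = 6.2e-07, and adjusted p = 0.31 with an estimated correlation. Basophil, mast cell and eosinophil genes had 5 of 16 tested members that fell, 0 that rose and 11 that did not pass, with the basophil protease Mcpt8 at 11.7 and 8.10 CPM in marrow and 0.139 in blood Ly6Clow. With p-values adjusted over the list alone, 0 rose and 8 fell, with camera adjusted p = 6.2e-07, and adjusted p = 0.39 with an estimated correlation. In the plasmacytoid dendritic cell list 1 of 13 tested members fell, 0 rose and 12 did not pass (adjusted over the list alone, 0 rose and 3 fell; camera adjusted p = 0.018, and adjusted p = 0.66 with an estimated correlation), a list call lost without marrow Ly6Clow 2 (adjusted p = 0.074) and reversed without blood Ly6Clow (0.94). In the T cell and NK cell list 2 of 22 tested members rose, 1 fell and 19 did not pass, with a median log2 value of 0.80 (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.0059, and adjusted p = 0.50 with an estimated correlation), a list call lost without blood Ly6Chi (0.25). None of the 20 macrophage genes passed in edgeR. Of these, 6 of 20 had an unadjusted p under 0.05 in edgeR, while 0 rose and 3 fell in DESeq2 and 1 rose and 6 fell in limma-voom (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.36, and adjusted p = 0.86 with an estimated correlation). None of the 13 genes of MHC class II presentation passed either. Here 2 of 13 had an unadjusted p under 0.05 in edgeR, while 1 rose and 1 fell in DESeq2 and 1 rose and 1 fell in limma-voom (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.70, and adjusted p = 0.90 with an estimated correlation). Without the blood Ly6Clow library, which leaves only Ly6Chi cells in the contrast, both lists were higher in blood. Without the blood Ly6Chi library, which leaves only Ly6Clow cells, both were lower in blood.

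In all, 652 of 18018 genes were higher and 445 lower in blood. With a replicate block, which leaves 2 residual degrees of freedom instead of 4, 3 were higher and 10 lower, and 12 of the 1097 calls were kept. The log2 fold of Nr4a1 was 2.33 ± 0.50 in that fit (adjusted p = 0.16). Left out 1 at a time, the libraries of marrow Ly6Chi 1, 2 and 3, marrow Ly6Clow 1 and 2, and blood Ly6Clow gave 245, 352, 349, 339, 330 and 1030 genes higher. Marrow Ly6Chi 1, 2 and 3, marrow Ly6Clow 2, blood Ly6Chi and blood Ly6Clow gave 166, 207, 262, 164, 846 and 942 genes lower when left out in the same way. The marrow Ly6Clow library 2 and the blood Ly6Chi library also had counts on 232 and 242 of 1037 olfactory receptor genes. The other libraries had counts on 13 to 47. A fit without both of them sets 1 blood Ly6Clow library against 1 marrow Ly6Clow library, and Ly6Chi cells no longer enter its contrast. Of the gate genes, Csf1r had a log2 value of 0.72 (adjusted p = 0.035), Itgax 2.06 (0.027), Ly6c2 -1.08 (0.030), Flt3 -0.41 (0.78), Kit -0.71 (0.29), Ly6c1 -0.19 (0.87) and Irf8 -0.21 (0.35). Csf1r lost its call without marrow Ly6Chi 1, 2 or 3, marrow Ly6Clow 2 or blood Ly6Chi (adjusted p = 0.074 to 0.19), Itgax without any 1 of these or marrow Ly6Clow 1 (0.052 to 0.12), and Ly6c2 without marrow Ly6Chi 1 or 3 or blood Ly6Clow (0.059 to 0.075). The examples above were picked, after their values were seen, among the 58 of 97 called named genes that kept their call whichever library was left out, and 39 did not.

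The blood Ly6Clow and blood Ly6Chi libraries, 1 of each, were set beside the marrow subsets as values, without a test of the blood libraries alone. Nr4a1 was at 2387 (2376 to 2398) CPM in blood Ly6Clow and 563 (558 to 568) in blood Ly6Chi. The exact Poisson 95% intervals in brackets are meant to cover counting error only. Each mate of a pair was counted, so counts are not independent and the intervals are too narrow even for that. Cd300e was at 1408 (1400.0 to 1417) and 9.48 (8.84 to 10.2) CPM, and S1pr5 at 744 (738 to 749.6) and 72.5 (70.7 to 74.3). Vcan was at 3.87 (3.45 to 4.33) CPM in blood Ly6Clow and 445 (441 to 449) in blood Ly6Chi, and Ly6c2 at 20.5 (19.5 to 21.5) and 761 (756 to 767). The MHC class II presentation genes H2-Aa and Cd74 lay closer together in blood than in marrow. H2-Aa was at 919 (913 to 926) and 515 (510.0 to 519.6) CPM and Cd74 at 3079 (3067 to 3092) and 1791 (1782 to 1800.0). Of the 6643 genes called between the marrow subsets, 4991 (75.1%) had the same direction between the blood libraries, against 55.8% of the genes not called in marrow.

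**Figure D4:**
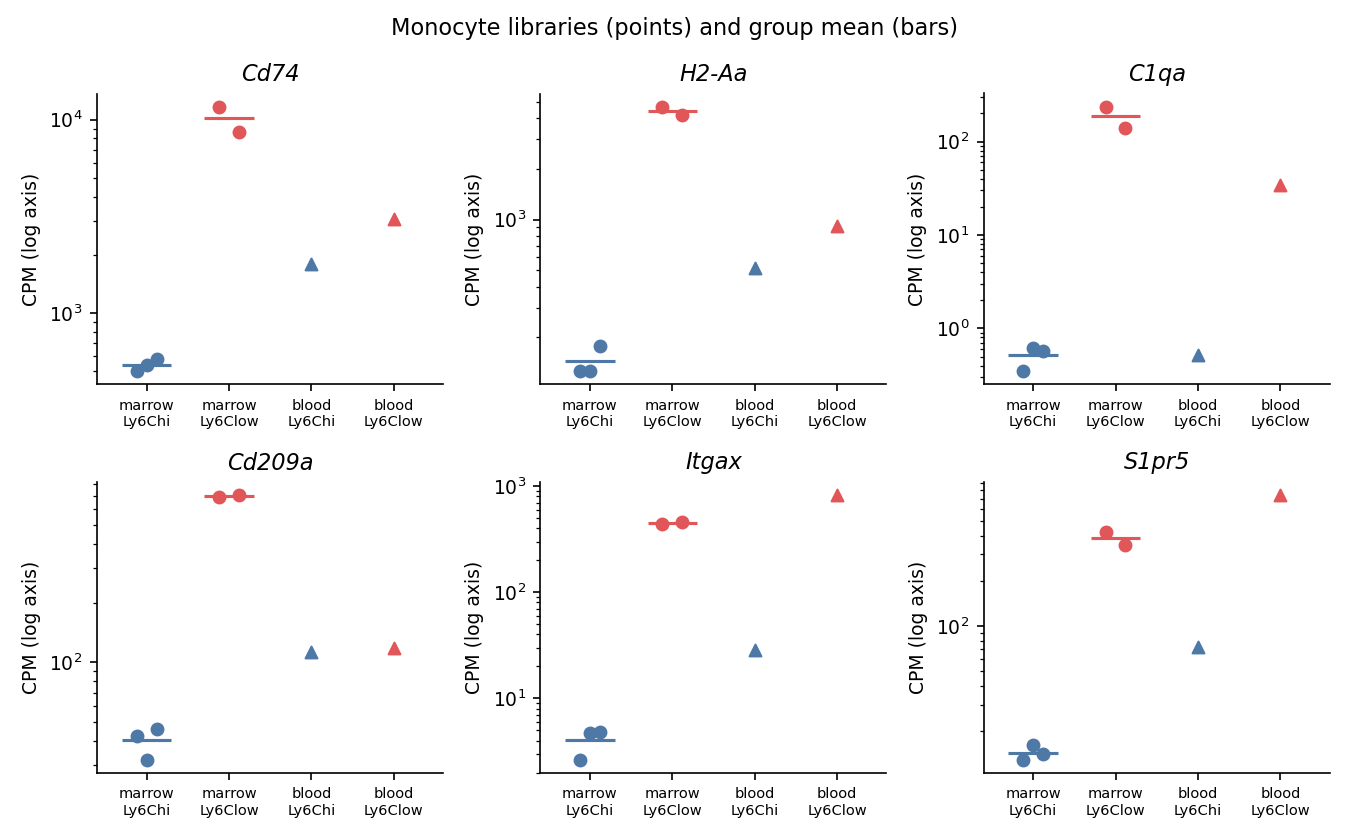
The genes Cd74, H2-Aa, C1qa, Cd209a, Itgax and S1pr5 in the 7 monocyte libraries, in CPM on a log axis, with points for libraries, bars for means of groups with more than 1 library, circles for marrow and triangles for blood. Cd209a was 686 and 704 CPM in the marrow Ly6Clow libraries and 118 in the blood Ly6Clow library, while Itgax was 436 and 454 CPM in the former and 820.0 in the latter.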

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

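The X to autosome ratio and the share held by the top genes were fixed before their values were seen; the thinning, marker share, replicate number and cell type tests, and the test of the difference between tissues, were chosen after the results were seen.

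The fold between Ly6Clow and Ly6Chi cells differed between blood and marrow for 38 of the 66 genes that the text prints for the marrow subsets, tested with an interaction term in edgeR over 11 libraries. Most of those genes were chosen by their marrow values, many for a large fold, which favors a smaller fold in blood. Among all 123 genes named for the marrow subsets by the rule, 53 differed, 43 below 0 and 10 above 0. The blood minus marrow difference of log2 folds was below 0 for 30 of the 38 and above 0 for 8, with adjusted p from 3.9e-06 to 0.042. The test assumes that each lone blood library varies like the marrow groups, and across the 19105 genes tested 1216 passed. Among MHC class II genes the difference was Cd74 (-3.46), H2-Aa (-4.10) and H2-Eb1 (-4.32). Macrophage and complement genes gave Mrc1 (-4.61), C1qa (-2.48), C1qb (-3.33) and C1qc (-2.30), and dendritic cell genes gave Clec10a (-3.47), Cd209a (-4.05), Mgl2 (-2.43), Cadm1 (-4.63) and Flt3 (-3.14). In lipid handling it was Cd36 (-2.08), Pltp (-1.91), Pparg (-1.79) and Nr1h3 (-2.00). The other genes below 0 were Lilra5 (-3.04), Il1b (-2.71), Cd300e (-2.41), Tgfbr3 (-2.05), Oasl1 (-2.37), Cd4 (-4.80), Dusp5 (-1.41), Eno3 (-1.23), Hes1 (-2.34), Slc12a2 (-0.90), Ccnd1 (-1.86), Cd274 (-0.95), S1pr5 (-1.39) and Klrd1 (-3.38). Those above 0 were Ctsg (4.59), Fn1 (2.59), Prtn3 (4.60), Cdc6 (3.15), Hal (5.30), Padi4 (2.5), Tyms (3.49) and Ccne1 (1.87). All 8 of these were lower in marrow Ly6Clow than in marrow Ly6Chi cells. Their folds therefore moved toward 0 or past it in blood. The genes below 0, except Oasl1, were higher in marrow Ly6Clow cells, and their folds also moved toward 0 or past it. Among the 38, Oasl1 alone had a larger fold in blood, and it was lower in Ly6Clow cells of both tissues. The sign of the difference therefore does not mark opposite patterns. The blood Ly6Clow and Ly6Chi libraries were at 30.8 and 65.7 CPM for Mrc1 and at 118 and 113 CPM for Cd209a. Some other genes were low in both, with Cd4 at 0.391 and 0.115 CPM, Cadm1 at 0.908 and 0.0923, and Tyms at 2.26 and 1.29.

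Olfactory receptor genes, which monocytes are not known to use, had counts at 232 of 1037 genes in marrow Ly6Clow library 2 and 242 in the blood Ly6Chi library, against 13 to 47 in the other 9 libraries. Deeper sequencing is argued against, since thinning every library to the smallest total still left 186.3 and 181.2 such genes, against at most 35.8 elsewhere. Transcripts of another cell type are argued against, since the top 1% of 2218 otherwise silent genes (23 genes) held 11.5% and 10.3% of the counts on them. Counts per kb on the X chromosome relative to autosomes were 0.474 (95% bootstrap interval 0.290 to 0.699) and 0.420 (0.285 to 0.587), near the ratio of 1 X copy in male cells, so genomic DNA is a candidate explanation. At 0.625 and 0.621 counts per kb of autosomal exon it would add little to the abundant genes named. It could add much to named genes near the floor in blood Ly6Chi, where 1 count is 0.0115 CPM, such as Asb2 (0.0231 CPM) and Cadm1 (0.0923 CPM). No explanation by the biology of the sorted cells themselves was tested, because the 2 libraries belong to different groups.

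All 23 Ly6Clow markers were higher in blood Ly6Chi cells than in the mean of marrow Ly6Chi cells, with a median log2 ratio of 1.93 (quartiles 1.11 to 2.63). Spn was only just so (426.8 against 423.4 CPM), and 22 of 23 were higher than in marrow Ly6Chi library 1. Blood Ly6Clow cells sorted with the Ly6Chi cells would bring the markers in at a like share of their blood Ly6Clow level. The share measured ran from 2.69% for Dusp16 to 63.6% for Cx3cr1 (median 11.2%, and 23.6% for Nr4a1, which is not among the 23). Of the 23 markers, 7 lay under 5.62%. The share includes what Ly6Chi cells express themselves, with Cx3cr1 at 494 CPM in marrow Ly6Chi cells, so its spread cannot decide on carry-over. A difference between replicate numbers that blood shared with marrow is argued against as the whole cause. Number 1 over number 2 in the 4 marrow populations had a median log2 ratio of 0.0945 over the 23 markers (quartiles -0.02 to 0.15). Nothing in the labels says that number 1 means the same in both tissues, so a difference of the lone blood library stays open. Carry-over may add a part, but at 1 share for all genes it is at most 0.721% of a gene's blood Ly6Clow level. This is the upper bound for Cd300e, the lowest of 2811 genes at 100 CPM or more there. It is somewhat low, since each mate of a pair was counted. The bound argues against carry-over as the whole cause over the 23 markers as a set. A tissue difference, which the design names, and a handling difference between blood and marrow samples, which goes with the tissue, stay open as untested.

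MHC class II, macrophage and dendritic cell genes were higher in marrow than in blood Ly6Clow cells, with a median log2 ratio of 1.79 for MHC class II, 2.12 for plasmacytoid dendritic cell genes (6 of 9 at least 1.5-fold higher in both marrow libraries) and -0.94 for the Ly6Clow markers. These values set 2 marrow libraries beside 1 blood library, without a test of the difference. B cells, which the CD19 lineage stain would remove, are argued against, with a median of -0.25 over their list. Of 15 conventional dendritic cell and 19 macrophage genes, 11 and 12 were at least 1.5-fold higher in both marrow libraries. Of all 10455 genes at 5 CPM or more in any of these libraries, 861 (8.2%) were so. The listed genes are those of the pattern, so their counts do not decide. Whether cells of any of these 3 types were in the marrow gate, which names no stain that would remove them, cannot be told apart from a tissue difference in the monocytes, which stays open as untested. The most abundant genes were far from trace levels, with Cd74 at 11680.0 and 8654 and Mrc1 at 316 and 316 CPM in marrow and 3079 and 30.8 in blood, but 15 and 14 of these members were also at 5 CPM or more in blood Ly6Clow cells.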

How the results depend on the processing

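The fit without both libraries that had more olfactory receptor genes was chosen after the data were seen, and the other alternatives were fixed before. Of 11919 values under an alternative, 10880 stayed the same, 806 no longer passed, 173 newly passed, 54 moved by more than the set margin and 6 reversed. A gene or list stayed the same if it kept its side of the threshold, and a count if it lay within the set margin. A change of direction was scored as reversed only where the main fit or the alternative called the gene or list. Named genes reversed by this rule in 0 of 20 settings per comparison. Of the called named genes, 86 of 117 in cMoP against MDP and 107 of 121 in Ly6Chi monocytes against cMoP were called in every setting. The counts were 108 of 123 in Ly6Clow against Ly6Chi and 0 of 97 in blood against marrow. That 0 was fixed by the fit without the subset term, which only blood against marrow had and which called 0 genes. Gene values that lost or gained a call numbered 117 and 15, 22 and 9, 28 and 0, and 529 and 116 in that order of comparisons, and list values 25 and 7, 22 and 12, 24 and 5, and 39 and 9. Upper-quartile scaling moved the median log2 fold by -0.10 in cMoP against MDP (1262 genes higher and 1763 lower) and by 0.10 in Ly6Clow against Ly6Chi (3865 and 2695).

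A minimum change, which by construction keeps fewer genes, gave 660 genes higher and 1018 lower (2-fold) and 552 higher and 732 lower (test against 1.5-fold) in cMoP against MDP. In Ly6Chi monocytes against cMoP it gave 2515 higher and 2449 lower at 2-fold, and 2602 and 2428 in the test against 1.5-fold. The figures for Ly6Clow against Ly6Chi were 2014 and 1249, and 1744 and 1192. Blood against marrow had 275 higher and 383 lower at 2-fold (41.8% higher, against 59.4% without a minimum), and 121 higher and 144 lower in the test against 1.5-fold. Fitting only the 2 groups compared gave 2337 genes lower in cMoP. Lists called with an estimated correlation numbered 0, 0, 1 and 0 in the 4 comparisons, and fry called 8 in blood against marrow. In blood against marrow, no filter gave 1439 genes higher and 1278 lower, DESeq2 1026 and 1095, and limma-voom 696 lower. Ly6Chi cells alone gave 1083 higher and 1487 lower, and Ly6Clow cells alone 937 and 1191, each with 1 blood library that is assumed to vary like the other groups. Without the subset term edgeR called 0 higher and 0 lower, with 2205 of 18018 genes at an unadjusted p under 0.05. Without both olfactory-rich libraries 226 genes were higher and 574 lower. For these values, apart from the minimum changes, the cause was not tested. The share of marrow calls with the same direction in blood was 77.1% on library totals, 76.9% at 5 CPM or more and 73.0% for changes of at least 2-fold.

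Leaving out 1 library at a time, with a group left at 1 library assumed to vary like the others, gave 668 to 1755 genes higher and 635 to 1640 lower in cMoP against MDP, and 3436 to 4670 genes higher and 3432 to 4907 lower in Ly6Chi monocytes against cMoP. The ranges were 2565 to 3333 genes higher and 2608 to 3477 lower in Ly6Clow against Ly6Chi, and 245 to 1030 genes higher and 164 to 942 lower in blood against marrow. Lists called ranged over 14 to 17, 22 to 23, 19 to 23 and 15 to 21. In blood against marrow 6 lists reversed. Without the blood Ly6Chi library camera's adjusted p was 0.36 for primary granule genes (0.018 with it) and 0.19 for interferon-stimulated genes (0.00023 with it). Leaving out blood Ly6Clow leaves only Ly6Chi cells in the tissue contrast, and leaving out blood Ly6Chi leaves only Ly6Clow cells. The reversals therefore set 1 subset beside the fit of both. Without blood Ly6Clow the direction reversed for MHC class II, macrophage, conventional and plasmacytoid dendritic cell genes (camera adjusted p = 0.70, 0.36, 0.36 and 0.018 with it). With each library left out in turn, these p-values ranged from 1.8e-07 to 0.36 for primary granule, 1.0e-13 to 0.19 for interferon-stimulated and 1.1e-07 to 0.94 for MHC class II genes. They ranged from 2.0e-06 to 0.87 for macrophage, 2.4e-05 to 0.67 for conventional dendritic cell and 4.9e-05 to 0.94 for plasmacytoid dendritic cell genes.

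Nothing in the labels says that replicate numbers pair the samples. Deviations from group means correlated at -0.06 to 0.16 (median 0.09) between libraries of the same number. In groups of 2 the deviations mirror each other, so some of these correlations repeat. Some genes did go with the number, with Hspa1a, Hspa1b, Jun and Fos higher in number 1 in 4 of 4 marrow populations. With a replicate block, 1833 genes were higher and 1660 lower in cMoP against MDP, 4419 and 4365 in Ly6Chi monocytes against cMoP, 3279 and 3529 in Ly6Clow against Ly6Chi, and 3 and 10 in blood against marrow, where both blood libraries have number 1. The replicate block gave 15, 23, 23 and 18 lists, and 12793 genes with any difference among marrow populations. All named genes of the 3 marrow comparisons kept their side of the threshold in the block, and 89 of 97 lost their call in blood against marrow. By construction the block leaves 2 residual degrees of freedom there instead of 4. The median SE of the 1097 calls went from 0.206 to 0.285 and their median absolute log2 fold was 1.23 in both, with 1097 keeping their direction. With 47206930 counts or more per library, a count of 0 allows at most about 0.0677 CPM.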

Other observations

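The comparison of replicate numbers given here was chosen after the data were seen.

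Some genes that regulate apoptosis changed between stages. Bcl2, which restrains mitochondrial apoptosis, was 285 ± 37.7 CPM in MDP, 68.4 ± 6.67 in cMoP, 6.26 ± 1.27 in marrow Ly6Chi and 57.5 ± 6.26 in marrow Ly6Clow cells (SD, n = 2, 2, 3 and 2). It fell in cMoP against MDP (log2 -2.06, adjusted p = 7.3e-05) and in Ly6Chi monocytes against cMoP (log2 -3.45, adjusted p = 1.1e-07), and rose in Ly6Clow against Ly6Chi cells (log2 3.21, adjusted p = 2.9e-07) and in blood against marrow (log2 1.71, adjusted p = 0.0028), all in edgeR. Mcl1, a related survival gene, rose from 203 ± 2.23 in cMoP to 783 ± 70.8 CPM in Ly6Chi monocytes (log2 1.95, adjusted p = 3.8e-07), and Pmaip1, which opposes it, rose from 19.0 ± 7.69 in marrow Ly6Chi to 142 ± 4.36 CPM in marrow Ly6Clow cells (log2 2.91, adjusted p = 1.3e-05). Over the list, 11 of 21 tested members rose, 3 fell and 7 did not pass in Ly6Chi monocytes against cMoP (adjusted over the list alone, 11 rose and 3 fell; camera adjusted p = 0.016, and adjusted p = 0.14 with an estimated correlation), and 6 of 21 tested members rose, 7 fell and 8 did not pass in Ly6Clow against Ly6Chi (adjusted over the list alone, 7 rose and 7 fell; camera adjusted p = 0.76, and adjusted p = 0.82 with an estimated correlation). In cMoP against MDP 4 of 21 tested members rose, 3 fell and 14 did not pass (adjusted over the list alone, 4 rose and 3 fell; camera adjusted p = 0.79, and adjusted p = 0.88 with an estimated correlation), and in blood against marrow 3 of 20 tested members rose, 0 fell and 17 did not pass (adjusted over the list alone, 9 rose and 0 fell; camera adjusted p = 0.0030, and adjusted p = 0.30 with an estimated correlation).

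Fc receptor and complement genes rose in Ly6Chi monocytes against cMoP for 13 of 20 tested members and fell for 2 (adjusted over the list alone, 13 rose and 2 fell; camera adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, went from 2.92 ± 0.525 to 86.7 ± 17.2 CPM (log2 4.89, adjusted p = 1.7e-07), and Itgam, the alpha chain of complement receptor Mac-1, from 121 ± 4.04 to 1203 ± 160.2 CPM (log2 3.31, adjusted p = 7.0e-08). The complement gene C3 had risen one step earlier, from 100.3 ± 58.6 CPM in MDP to 756 ± 83.0 in cMoP (log2 2.91, adjusted p = 0.00023).

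Libraries numbered 1 were set against those numbered 2 over the 4 marrow populations (8 libraries, edgeR with a term for population). Of 17679 genes, 7 were called, 5 higher and 2 lower in number 1, and 1098 had an unadjusted p under 0.05. They were Hspa1a (log2 4.39, adjusted p = 3.4e-06, 17.6 to 25-fold in 4 of 4 populations), Hspa1b (log2 3.71, adjusted p = 7.3e-06, 9.66 to 15.8-fold), Jun (log2 1.90, adjusted p = 0.0033), Fos (log2 1.65, adjusted p = 0.0033), Gm10382 (log2 3.10, adjusted p = 0.0051), Capn11 (log2 -5.36, adjusted p = 0.0049) and Siglech (log2 -1.34, adjusted p = 0.034). Hspa1a and Hspa1b are near-identical copies. Nr4a1 had a log2 difference of -0.00 (adjusted p = 0.996) and Dusp1 1.12 (adjusted p = 0.36).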
